A study of Mus musculus with 16 samples.

How the data were processed

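Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in 16 libraries of E14 mouse embryonic stem (ES) cells. There were 4 genotypes with 4 replicates each: wild type (WT), AID-Zzz3, AID-Yeats2 and Supt7l knockout (KO). Zzz3 and Yeats2 are subunits of the ATAC complex and Supt7l is a subunit of the SAGA complex, both of which are histone acetyltransferase coactivators. In the AID lines the protein carries an auxin-inducible degron, a tag through which auxin triggers degradation. Per the labels, all cells including WT received auxin for 24 h and were grown without feeder cells in serum with 1500 U/ml LIF, 3 µM CHIR99021 and 1 µM PD0325901. Each library came from 100000 cells, 25 nM Tn5 and 14 PCR cycles, sequenced as paired reads of 100 bp.

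The authors named Bowtie2 2.2.6, MACS2 2.1.1.20160309, HOMER, bedtools 2.26.0 and DESeq2 1.16.1, with the mouse build mm10. The deposited table holds 1 merged list of 70150 peaks with raw counts per peak and library. It also holds the log2 fold changes and the adjusted p-values of the authors' own DESeq2 comparisons, which the deposited header names. The distance to the nearest Ensembl transcription start site (TSS), in bp, and the feature at each peak come from the authors' HOMER annotation. The 16 columns of normalised values per library, a rescaled copy of the counts, were not used. Peak names carry starts counted from 0, and all starts are given here counted from 1.

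Counts were fitted with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests (two-sided) on all 16 libraries together, with TMM scaling and the filterByExpr filter, which left 69692 peaks and removed 458. A peak was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested peaks. Each mutant was compared with WT, AID-Yeats2 with AID-Zzz3, and the mean of both ATAC lines with Supt7l KO. Levels are counts-per-million of the library's TMM-scaled counts in peaks (CPM; unscaled for chromosome Y), as mean ± SD of 4 libraries. CPM of single peaks and log2 values per library used a prior count of 2. The series text speaks of 2 independent clones and of 2 experiment days, but its sample numbers do not cover the 16 libraries, so no clone or day was assigned to a library and the main design had no covariate. The tests and SDs treat the 4 libraries of a line as independent, although they may come from 2 clones. Unless another test is named, every adjusted p of a peak is from edgeR. A promoter peak lay within 1000 bp of a TSS, and windows of 500 and 3000 bp were also tried. Values of groups of peaks per library were compared by exact permutation tests (two-sided), for which 4 libraries against 4 allow no p below 0.0286.

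For gene lists, 1 promoter peak per gene was used (15557 genes), the one with the highest mean. The 29 lists covered naive pluripotency, formative and primed pluripotency, primitive endoderm, trophoblast, mesendoderm, neuroectoderm, fibroblast, 2-cell-like and germ line markers, SAGA subunits, ATAC subunits, general transcription factors, replication-dependent histones, ribosome biogenesis, aminoacyl-tRNA synthetases, unfolded protein and amino acid stress, p53 targets, cell cycle, glycolysis, cholesterol synthesis, lysosome and autophagy, WNT targets, FGF and ERK targets, TGF-beta, BMP and LIF targets, Hox genes, imprinted genes, ubiquitous reference genes, the mitochondrial ribosome and cytoplasmic ribosomal proteins. They named 832 genes, each counted once, of which 614 were measured. A list with at least 5 measured members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, which compares a list with all other promoters, adjusted over the 84 tests of 28 lists in 3 comparisons. Camera with an estimated correlation and fry, which asks whether a list moves as a whole, were the alternatives. The 2-cell-like list had 4 measured members and was not tested.

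The peaks named in the text were chosen by a rule fixed, with the lists, comparisons and most alternative settings, before the data were examined. It took every peak at Zzz3, Yeats2 and Supt7l. It took the 10 higher and 10 lower peaks with the largest log2 fold change among called peaks that lay above the median level and had all 4 mutant libraries on the same side of all 4 WT libraries, 1 per nearest gene, with predicted genes left out. From each list with a called member it took the 3 members with the smallest adjusted p. A few further loci are named as chosen after their values were seen. A few peaks that this rule chose are counted in the totals but not reported here.

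Chromosomes were compared by the median log2 value of their peaks per library against the WT mean, called when all 4 libraries of a genotype moved the same way by over 0.2. Bins of 10 Mb with at least 20 peaks were treated the same way. The correlation of fold changes between comparisons was set beside 20 simulated draws of unchanged groups against the same WT libraries and beside fits that gave each mutant its own WT libraries. Recovery was tested on simulated data with 200 changed peaks (edgeR). At 2-fold, 50.7% of the changed peaks were found for AID-Zzz3, 61.2% for AID-Yeats2 and 53.7% for Supt7l KO, and at 1.5-fold 19.4%, 8.96% and 13.4%. False calls numbered 2, 1 and 14 of 69692 peaks. The 14 of Supt7l KO stood beside 9, 36 and 52 true calls at 1.5-fold, 2-fold and 3-fold. The simulated libraries were independent, without shared deviations between replicates.

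The alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals without a TMM factor, loess offsets, no filter beyond 1 count, a mean count of at least 50, only the groups of a comparison in the fit, blocks for replicates, leaving out each library in turn, an adjusted p under 0.01 and a change of at least 1.5-fold. Fits without 3 genomic regions, within replicates 1 and 2 or 3 and 4, and with loess offsets joined to a block were added after the data were seen. Between all 24 pairs of replicates of a genotype, the correlation of log2 values was 0.859 to 0.926, so no library was a copy of another of its genotype. Motif shares were not computed because they need the mm10 sequence, which was not at hand.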

Results

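The data describe accessible chromatin in 16 ATAC-seq libraries of mouse ES cells: 4 WT, 4 AID-Zzz3, 4 AID-Yeats2 and 4 Supt7l KO. Counts in peaks came to 2492045 to 5540559 per library. The group means were 4873579 ± 684319 for WT, 3633234 ± 512378 for AID-Zzz3, 3632302 ± 971776 for AID-Yeats2 and 4048807 ± 682917 for Supt7l KO (SD, n = 4). The AID-Zzz3 libraries were smaller than those of WT (exact permutation p = 0.0286), and the other lines gave an exact permutation p of 0.114 (AID-Yeats2) and 0.143 (Supt7l KO). The median peak was 706 bp wide, and 27% of the 69692 tested peaks lay at promoters. Replicates 1 and 2 of all lines shared deviations from their group means, as did replicates 3 and 4 (all 48 correlations within these sets positive, 0.0163 to 0.111, and all 48 between them negative, -0.109 to -0.0167). The promoter shift and the counts of peaks are therefore also given within these sets.

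AID-Zzz3 was compared with WT to ask which accessible regions depend on this ATAC subunit. In AID-Zzz3, promoters lost accessibility relative to the rest of the genome, while single sites in introns and between genes gained it. CpG-annotated peaks over 3000 bp from a TSS moved the same way (-0.18), so the loss was not confined to peaks near an annotated TSS. Whether some of these peaks are unannotated promoters was not tested. Degradation of the protein itself was not measured here. Promoters of cytoplasmic ribosomal protein genes were called lower as a group, a call lost with an estimated correlation (camera, adjusted p = 0.441). A site in an intron of Fam160a1 was 2.89-fold higher. Of all tested peaks, 442 were higher and 241 lower than in WT (edgeR, adjusted p under 0.05), 253 of them by over 2-fold. With a block for replicates 1 and 2 against 3 and 4 there were 781 and 508. Promoters made up 62.7% of the lower peaks (151 of 241; Fisher's exact test, adjusted p = 1.98e-30) and 13.1% of the higher ones (58 of 442; 2.07e-12), against 27% of all tested peaks. Per library, the median promoter value minus that of other peaks was -0.15 ± 0.060 on the log2 scale, against -0.0052 ± 0.031 in WT (SD, n = 4; exact permutation p = 0.0286). The difference was -0.096 within replicates 1 and 2 and -0.20 within replicates 3 and 4.

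Higher peaks that kept their call whichever library was left out lay in introns of Fam160a1 (ENSMUSG00000051000; chromosome 3, 85637861 to 85639030; 19.3 ± 4.77 CPM against 6.85 ± 2.19 in WT; log2 change 1.53, adjusted p = 1.36e-04) and of Dock10, a guanine nucleotide exchange factor (chromosome 1, 80622540 to 80623442; 17.6 ± 4.53 against 7.27 ± 0.613 CPM; 1.32, adjusted p = 0.00150). The same held for introns of Ice1, a component of the little elongation complex (1.31), of the kinesin gene Kif16b (1.21) and of the axonemal dynein gene Dnah5 (1.19), and for intergenic sites near Nanos1 (1.17) and Tmem14a (1.157). Lower peaks of this kind lay near the small nucleolar RNA gene Snord83b (ENSMUSG00000077734; chromosome 15, 80075242 to 80077449; 30.3 ± 5.92 against 55.9 ± 3.45 CPM; -0.89, adjusted p = 3.14e-04), in an intron of Lrch1 (-0.98) and at promoters of the splicing gene Usp39 (-0.96) and the Golgi adaptor gene Gga1 (-0.90). Of 29 chosen results in this comparison, 13 kept their call in all 8 fits that left out 1 library and 16 lost it in at least 1. Among the higher ones, AC130844.1 (1.22) lost it without AID-Zzz3 4 (adjusted p = 0.0527) and Pcdh15 (1.10) without AID-Zzz3 1 (0.0557). Among the lower ones, Cmtr1 (-0.96) lost it without WT 2 or AID-Zzz3 1 (adjusted p 0.103 to 0.104), and Platr4 (-0.94) without WT 3 or AID-Zzz3 4 (0.0507 to 0.0513). Prickle2 (-0.96) lost it without WT 2 or 4 or AID-Zzz3 1 or 3 (adjusted p 0.0584 to 0.0965), and Ift88 (-0.97) without WT 3 or 4 or AID-Zzz3 1, 3 or 4 (0.0579 to 0.169). Nudt4 (-0.96) lost it without WT 1, 3 or 4 or AID-Zzz3 1, 3 or 4 (adjusted p 0.0532 to 0.144), and Cerkl (-0.91) without any WT library or AID-Zzz3 1, 3 or 4 (0.0606 to 0.209).

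Of 73 measured cytoplasmic ribosomal protein promoters, 3 passed the test over all peaks and 15 when adjusted over the list alone, all lower (median -0.24 against -0.11 for all promoters). Camera called this list lower (adjusted p = 3.19e-05), and the adjusted p = 0.441 with an estimated correlation. Rpl10a reached 18.4 ± 3.38 CPM against 31.3 ± 6.63 in WT (chromosome 17, 28328030 to 28329346; log2 change -0.79, adjusted p = 0.00721), and Rps15 changed by -0.69. These calls were lost for Rpl10a without WT 1 or AID-Zzz3 4 (adjusted p 0.0515 to 0.0804) and for Rps15 with loess offsets (0.0650) and without WT 1, 2 or 4 or AID-Zzz3 2, 3 or 4 (0.0660 to 0.235). Lysosome and autophagy promoters (24 measured, median -0.22) were called lower by camera (adjusted p = 0.0349; adjusted p = 0.525 with an estimated correlation, 0.102 with loess offsets, 0.0602 without chromosome Y and the distal blocks of chromosomes 14 and 17), with 2 members called over all peaks and 6 adjusted over the list alone, none higher. They included the lysosomal hexosaminidase gene Hexa (15.4 ± 1.68 against 27.6 ± 3.48 CPM; -0.86, adjusted p = 0.00488) and the autophagy gene Wipi2 (-0.63; lost without WT 1, 3 or 4 or AID-Zzz3 3 or 4, adjusted p 0.0507 to 0.135). Ribosome biogenesis promoters (35 measured, median -0.22) were also called lower (adjusted p = 0.0134; adjusted p = 0.547 with an estimated correlation, 0.0693 with loess offsets), with 0 members called over all peaks and 2 adjusted over the list alone.

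Single members of other lists passed the test in AID-Zzz3. Klf5, a transcription factor of naive pluripotency, fell at its promoter (ENSMUSG00000005148; chromosome 14, 99298220 to 99299430; 54.1 ± 6.20 against 80.7 ± 22.9 CPM; log2 change -0.57, adjusted p = 0.00972), a call lost without WT 4 (-0.37, adjusted p = 0.168). Zic5 fell by 0.46 (adjusted p = 0.0433), lost without WT 1 or 4 or any AID-Zzz3 library (0.0549 to 0.207), with library totals alone (0.0529) and with loess offsets (0.125). Klf5, Zic5 and Lrch1 lie in the distal part of chromosome 14, which shifted as a block between libraries, WT included. Vars, the valyl-tRNA synthetase gene, fell by 0.86 (adjusted p = 0.0130), lost without WT 1 or AID-Zzz3 3 or 4 (0.0531 to 0.0863). The imprinted noncoding RNA gene Peg13 was 3.36-fold higher by the fitted means (ENSMUSG00000106847; chromosome 15, 72809120 to 72810854; log2 change 1.75, adjusted p = 4.14e-04; DESeq2 0.0791). Its libraries differed widely, however, at 58.4, 6.28, 62.4 and 12.5 CPM against 10.6 ± 1.68 in WT (SD, n = 4). The other 25 lists gave camera adjusted p-values of 0.0706 to 0.982.

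No peak at the targeted genes differed between AID-Zzz3 and WT. The 5 peaks at Zzz3 had log2 changes of -0.46 to 0.36 (smallest adjusted p = 0.103). Within replicates 1 and 2 alone the counts were 16 higher and 9 lower, and within replicates 3 and 4 alone 222 and 200. Leaving out 1 library changed the count of higher peaks to 162 (WT 1), 196 (WT 4), 289 (AID-Zzz3 1), 146 (AID-Zzz3 3) or 218 (AID-Zzz3 4), and that of lower peaks to 84 (WT 1), 70 (WT 4), 133 (AID-Zzz3 1), 363 (AID-Zzz3 2), 79 (AID-Zzz3 3) or 98 (AID-Zzz3 4). Higher peaks were 64.7% of the calls, and 75.5% with loess offsets.

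**Figure D1:**
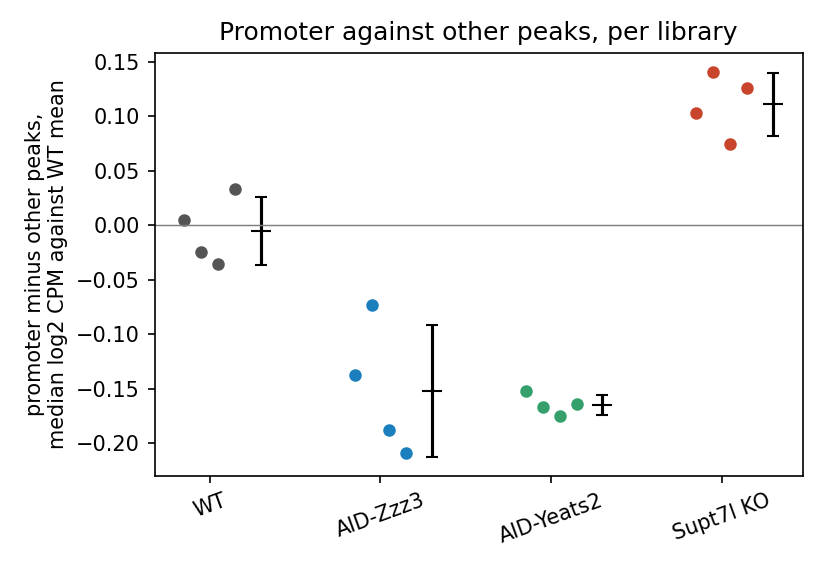
Median log2 CPM of promoter peaks minus that of other peaks, each against the WT mean, with 1 point per library and the mean ± SD of each genotype (n = 4). All AID-Zzz3 and AID-Yeats2 libraries lie below all WT libraries, and all Supt7l KO libraries lie above them.

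AID-Yeats2 was compared with WT to ask the same of another ATAC subunit. In AID-Yeats2, promoters again lost accessibility relative to other regions. Ribosomal protein genes and cell cycle genes were called lower as groups, calls lost with an estimated correlation (camera, adjusted p = 0.441 and 0.525). The phosphatase subunit gene Ppp2r2a and the RNA surveillance gene Zcchc8 were lower at their promoters, and introns of Fam160a1, Ttc7b and Utp20 were higher. In total 365 peaks were higher and 208 lower (edgeR), and 707 and 496 with a block for replicates 1 and 2 against 3 and 4. Promoters made up 67.8% of the lower peaks (141 of 208; Fisher's exact test, adjusted p = 1.01e-33) and 10.7% of the higher ones (39 of 365; 4.82e-14). The promoter value minus that of other peaks was -0.16 ± 0.0092 (SD, n = 4), and its difference from WT was -0.16 (exact permutation p = 0.0286), with -0.15 within replicates 1 and 2 and -0.17 within replicates 3 and 4.

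The intron of Fam160a1 reached 18.99 ± 4.85 CPM against 6.85 ± 2.19 in WT (log2 change 1.49, adjusted p = 2.05e-04). Introns of Ttc7b (1.30), the ribosome biogenesis gene Utp20 (1.28; 15.95 ± 2.33 against 6.75 ± 1.199 CPM, adjusted p = 0.00126), Unc80 (1.24), Kif16b (1.22), Fgl1 (1.19), Ice1 (1.14) and the peptidase gene Tpp2 (1.12) were also higher and kept their call whichever library was left out. So did an intron of Rb1, the retinoblastoma tumour suppressor gene (ENSMUSG00000022105; chromosome 14, 73312941 to 73313732; 13.9 ± 2.101 against 6.21 ± 0.540 CPM; 1.23, adjusted p = 0.00197). Lower promoters that kept their call in these fits were those of Ppp2r2a (ENSMUSG00000022052; chromosome 14, 67071832 to 67073005; 22.6 ± 1.77 against 43.8 ± 12.0 CPM; -0.98, adjusted p = 1.70e-04), Poldip3 (-1.10) and Zcchc8 (-0.96; 14.5 ± 3.94 against 27.1 ± 1.94 CPM). Ppp2r2a, Rb1, Lacc1, Spry2 and Klf5 lie in the distal block of chromosome 14. Of 28 chosen results, 12 kept their call in all 8 fits that left out 1 library and 16 lost it in at least 1. Mier3 (-1.07) lost it without WT 1 or AID-Yeats2 2 or 4 (adjusted p 0.0533 to 0.0608), Tm7sf3 (-0.91) without AID-Yeats2 1, 2 or 4 (0.0509 to 0.0660) and Fchsd2 (-0.97) without WT 4 or AID-Yeats2 1, 3 or 4 (0.0507 to 0.100). The microRNA-processing gene Dicer1 (-0.97) lost it without WT 1 or 4 or AID-Yeats2 2, 3 or 4 (adjusted p 0.0636 to 0.135), and Lacc1 (-0.90) without WT 3 or 4 or AID-Yeats2 1 or 3 (0.0601 to 0.111). Ndufs6b (-0.91) lost it without WT 1 or 4 or AID-Yeats2 1, 2 or 4 (adjusted p 0.0641 to 0.166), and the tumour suppressor gene Nf2 (-0.92) without WT 1, 3 or 4 or any AID-Yeats2 library (0.0574 to 0.227) and with library totals alone (0.0574).

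Camera called ribosomal protein promoters lower in AID-Yeats2 (adjusted p = 2.86e-04), and the adjusted p = 0.441 with an estimated correlation. Their median was -0.24 against -0.12 for all promoters, with 4 of 73 called over all peaks and 15 when adjusted over the list alone, none higher. Rpl10a fell by 0.73, lost without WT 1 or 4 or AID-Yeats2 3 or 4 (adjusted p 0.0510 to 0.128). Rps6 fell by 0.52, lost without WT 1, 2 or 4 or AID-Yeats2 2, 3 or 4 (adjusted p 0.0710 to 0.116) and with loess offsets (0.129). Cell cycle promoters (34 measured, median -0.21) were called lower (camera adjusted p = 0.0103; adjusted p = 0.525 with an estimated correlation, 0.138 with loess offsets), with 1 member called over all peaks and 5 adjusted over the list alone. The called member was Cdc25a, a phosphatase that drives entry into S phase (29.2 ± 5.77 against 43.2 ± 4.60 CPM; -0.60, adjusted p = 0.0230), lost without WT 1 or 4 or AID-Yeats2 2 or 3 (adjusted p 0.0772 to 0.133) and with loess offsets (0.0845).

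Imprinted genes were called higher relative to other promoters in AID-Yeats2 (26 measured, median 0.11; camera adjusted p = 0.00574, adjusted p = 0.254 with an estimated correlation). Against no change, rather than against other promoters, fry gave an adjusted p = 0.199. Over all peaks 1 member was higher and 1 lower, and 2 and 1 when adjusted over the list alone. Peg13 reached 24.5 ± 4.34 CPM against 10.6 ± 1.68 (log2 change 1.26, adjusted p = 0.0204; DESeq2 0.293), a call lost without WT 1 or 4 or AID-Yeats2 1, 2 or 3 (adjusted p 0.0538 to 0.0867). Inpp5f fell by 0.50 (adjusted p = 0.0462), lost without any of the 8 libraries (0.0681 to 0.172), with library totals alone (0.0618) and with loess offsets (0.171). Klf5 fell by 0.49 (adjusted p = 0.0360; DESeq2 0.0784), but by 0.29 without WT 4, and lost its call without WT 1 or 4 or any AID-Yeats2 library (0.0657 to 0.340) and with loess offsets (0.190). The FGF feedback inhibitor gene Spry2 fell by 0.62 (adjusted p = 0.0169), lost without WT 1 or 4 or AID-Yeats2 2 or 3 (0.0652 to 0.132) and with loess offsets (0.0631). Mrto4, of the ribosome biogenesis list, fell by 0.77 (adjusted p = 0.0309), lost without WT 1 or 4 or AID-Yeats2 2 or 3 (0.0606 to 0.156). The other 25 lists gave camera adjusted p-values of 0.0683 to 0.875.

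The 6 peaks at Yeats2 had log2 changes of -0.22 to 0.23 in AID-Yeats2 (smallest adjusted p = 0.720). On the same chromosome, and chosen after its values were seen, a peak near Gm20614 (chromosome 16, 20431677 to 20431880) held 11, 14, 12 and 14 counts in AID-Yeats2 against 2, 1, 2 and 0 in WT and 5, 5, 4 and 2 in AID-Zzz3 (AID-Yeats2 against WT, adjusted p = 6.07e-04). Within replicates 1 and 2 alone 11 peaks were higher and 11 lower, and within replicates 3 and 4 alone 90 and 40. Leaving out 1 library changed the count of higher peaks to 143 (WT 1), 127 (WT 4), 149 (AID-Yeats2 2), 209 (AID-Yeats2 3) or 169 (AID-Yeats2 4), and that of lower peaks to 52 (WT 1), 40 (WT 4), 64 (AID-Yeats2 2), 87 (AID-Yeats2 3) or 92 (AID-Yeats2 4). Higher peaks were 63.7% of the calls, 76.9% with library totals alone and 78.0% with loess offsets.

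AID-Yeats2 and AID-Zzz3 were compared to ask whether the loss of either ATAC subunit differs from that of the other. No peak differed between them at an adjusted p under 0.05 with edgeR (smallest 0.433), and DESeq2 also gave 0. An unadjusted p under 0.05 was reached by 3572 of 69692 peaks (3252 with DESeq2), close to the share that chance alone gives. With a block for replicates 1 and 2 against 3 and 4 it was reached by 4175, and 0 were called (edgeR, smallest adjusted p = 0.147). Recovery of simulated changes was not tested for this contrast, so the absence of calls does not show that the lines are the same. Without AID-Zzz3 4 the count was 1. Both lines shared 169 higher peaks, among them those of Fam160a1, Kif16b, Ice1 and Peg13, and 63 lower ones, among them Rpl10a and Klf5. Ice1 was not particular to these lines. Supt7l KO stood above WT there by 0.86 (edgeR, adjusted p = 0.0551), and the ATAC lines did not differ from Supt7l KO (0.37, adjusted p = 0.190). Fam160a1, Kif16b and Peg13 gave -0.14, -0.21 and -0.26 in Supt7l KO against WT. In 20 simulations of unchanged groups that share WT no peak was shared, though such groups yield few calls. No peak was called in opposite directions in AID-Zzz3 and AID-Yeats2. Across peaks, which are not independent replicates, the fold changes correlated with r = 0.662 (rho = 0.641), against a mean of 0.466 in 20 simulations of unchanged groups that share WT, and with 0.286 to 0.355 in 6 fits that gave each line its own WT libraries.

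Supt7l KO was compared with WT to ask which regions depend on a core SAGA subunit. With Supt7l lost, more peaks were lower than higher, and most of the lower ones lay outside promoters. The imprinted genes Meg3, Plagl1 and Nap1l5 lost 4.16-fold, 2.84-fold and 2.11-fold, and the urate transporter gene Slc2a9 lost 2.54-fold at an intronic site. Plagl1, Nap1l5 and further peaks of the Meg3 locus also differed between WT libraries. Whether these losses go with the genotype or with the clone was not tested. Promoters as a class rose relative to other regions, the opposite of the ATAC lines. All 7 peaks of chromosome Y were nearly empty, and long distal segments of chromosomes 14 and 17 shifted as blocks. In total 238 peaks were higher and 519 lower (edgeR), 332 of them by over 2-fold, and 413 and 769 with a block for replicates 1 and 2 against 3 and 4.

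Promoters made up 13.3% of the lower peaks (69 of 519; Fisher's exact test, adjusted p = 8.10e-14) and 39.1% of the higher ones (93 of 238; 5.28e-05). The latter share was 24.2% with loess offsets (Fisher's exact test, p = 0.409) and 15.9% without the peaks of chromosome Y and of the distal blocks (p = 0.0414), below the 27% of all tested peaks. The shift of promoters as a class did not rest on calls. Promoter minus other peaks was 0.11 ± 0.029 per library, a difference from WT of 0.12 (SD, n = 4; exact permutation p = 0.0286), with 0.13 within replicates 1 and 2 and 0.10 within replicates 3 and 4.

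Imprinted genes were called lower relative to other promoters in Supt7l KO (26 measured, median -0.020, mean -0.15, all promoters 0.090; camera adjusted p = 0.00126, adjusted p = 0.223 with an estimated correlation), with 2 members called over all peaks and 3 adjusted over the list alone, none higher. Meg3, a maternally expressed noncoding RNA gene, fell to 3.79 ± 0.155 CPM from 14.3 ± 1.73 (ENSMUSG00000021268; chromosome 12, 109542730 to 109543791, exon; log2 change -2.06, adjusted p = 1.78e-07). Chosen after their values were seen, 3 further peaks of this locus were lower. The peak upstream of Meg3 (109538791 to 109539446) held 6, 2, 0 and 2 counts against 34, 60, 64 and 22 in WT (adjusted p = 3.39e-09). That at Gm34081 (-1.73) held 15, 6, 11 and 11 against 41, 55, 61 and 23. That at Gm27528 (-2.15) held 7, 7, 4 and 4 against 16, 55, 43 and 8. At all 3, WT 2 and 3 stood above WT 1 and 4. Nap1l5 fell to 14.4 ± 1.03 from 29.6 ± 8.01 CPM (ENSMUSG00000055430; chromosome 6, 58906430 to 58907681, promoter; -1.08, adjusted p = 5.99e-05). Plagl1, an imprinted transcription factor gene, fell to 12.0 ± 4.14 from 32.7 ± 14.0 CPM at its promoter (ENSMUSG00000019817; chromosome 10, 13090269 to 13091507; -1.51, adjusted p = 5.95e-05; DESeq2 0.0505). In the list Plagl1 is represented by another promoter peak with a higher mean, from 13060354, which was not called (0.11, adjusted p = 0.833). Meg3, Nap1l5 and Plagl1 kept their edgeR call whichever library was left out, a check that cannot test differences between clones. By library, Plagl1 stood at 22.3, 48.8, 39.9 and 19.85 CPM in WT and at 49.8, 17.6, 41.6 and 16.75 in AID-Zzz3. Nap1l5 stood at 19.9, 33.8, 38.1 and 26.8 CPM in WT.

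**Figure D2:**
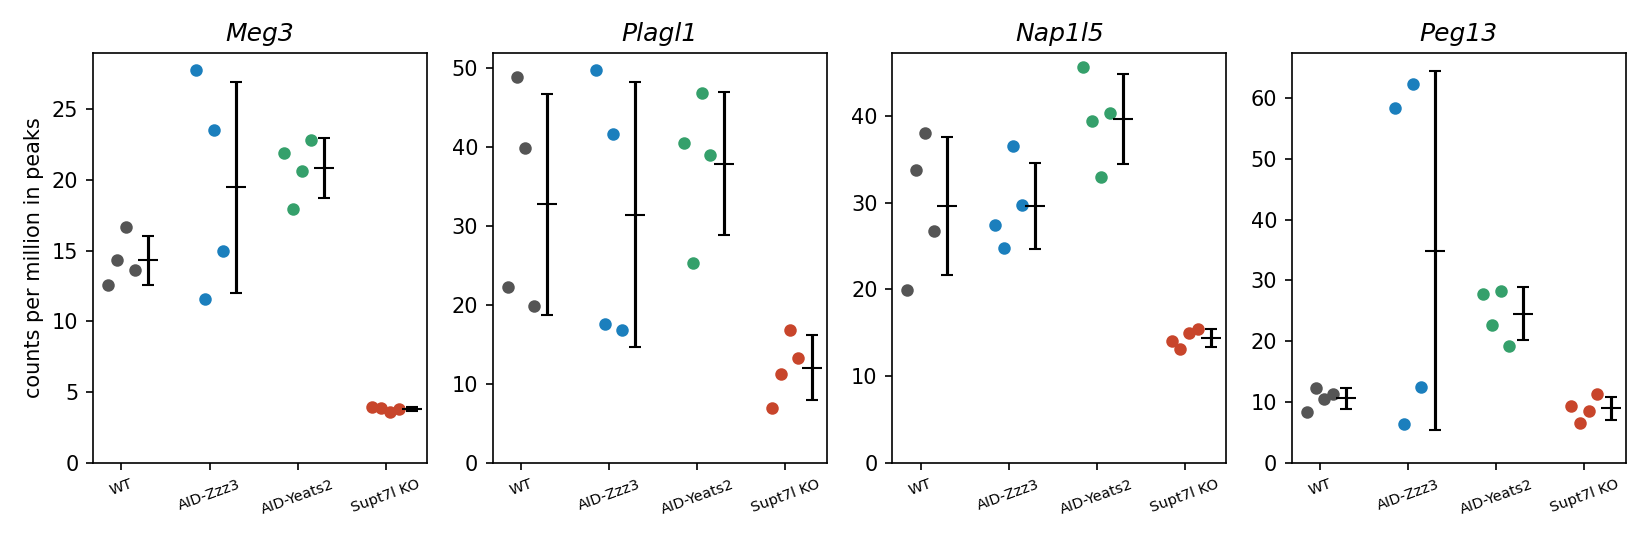
Normalised accessibility of 1 peak each at the imprinted genes Meg3, Plagl1, Nap1l5 and Peg13, in CPM (prior count of 2), with 1 point per library and the mean ± SD of each genotype (n = 4). Supt7l KO lies below WT at Meg3, Plagl1 and Nap1l5, and the AID-Zzz3 libraries lie far apart at Peg13.

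Other lower sites that kept their call in every such fit were an intron of Slc2a9 (ENSMUSG00000005107; chromosome 5, 38493910 to 38495338; 10.2 ± 0.901 against 25.2 ± 1.1996 CPM; log2 change -1.35, adjusted p = 2.28e-07), an intergenic site near Dcdc2a (8.27 ± 2.06 against 22.8 ± 3.83 CPM; -1.54, adjusted p = 2.76e-07) and an intron of Tril (-1.50). The same held for sites near the mismatch repair gene Msh6 (-1.79), Galm (-1.48) and Ltbp1 (-1.34). These last 3 lie in the distal block of chromosome 17, as does Rmdn2 (-1.199), whose call was lost without WT 2 or 3 (adjusted p 0.0558 to 0.184). Higher sites that kept their call were the intron of Rb1 (15.8 ± 2.18 against 6.21 ± 0.540 CPM; 1.40, adjusted p = 7.96e-05), the 5S ribosomal RNA gene n-R5s48 (0.98), an intron of the axon guidance receptor gene Robo1 (0.97) and an intron of the splicing regulator gene Mbnl2 (0.97). Of these, Rb1, n-R5s48 and Mbnl2 lie in the distal block of chromosome 14, as do Mycbp2 and Tbc1d4. Of 25 chosen results, 14 kept their call in all 8 fits that left out 1 library and 11 lost it in at least 1. Kazn (1.06) lost it without WT 2 or 3 (adjusted p 0.0536 to 0.0622), Camsap3 (1.00) without WT 2 (0.0619), Rin3 (0.98) without WT 3 (0.0518) and Tbc1d4 (0.95) without WT 3 (0.0622). Mycbp2 (0.98) lost it without WT 2 or 3 or Supt7l KO 2, 3 or 4 (adjusted p 0.0544 to 0.0832), and Tenm4 (0.97) without WT 2 or 3 or Supt7l KO 4 (0.0764 to 0.109).

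Among gene lists, p53 target promoters were called higher (25 measured, median 0.19 against 0.090 for all promoters; camera adjusted p = 0.0103, adjusted p = 0.441 with an estimated correlation, 0.0839 with loess offsets). The exonuclease gene Aen passed over all peaks (44.7 ± 3.73 against 29.8 ± 3.05 CPM; log2 change 0.59, adjusted p = 0.0118), lost without WT 3 or Supt7l KO 4 (0.0539 to 0.0885), and 4 members passed when adjusted over the list alone, none lower. Promoters of unfolded protein and amino acid stress genes were called higher (23 measured, median 0.16; camera adjusted p = 0.0463, adjusted p = 0.441 with an estimated correlation, 0.280 with loess offsets), with 0 members over all peaks and 3 over the list alone. Replication-dependent histone promoters (29 measured, median 0.18; camera adjusted p = 0.0103) and ribosomal protein promoters (73 measured, median 0.20; camera adjusted p = 0.00574) were called higher with 0 members called over all peaks or adjusted over the list alone. Their adjusted p = 0.441 and adjusted p = 0.547 with an estimated correlation. Klf5 rose by 0.52 (115.0 ± 20.9 against 80.7 ± 22.9 CPM; adjusted p = 0.0119), with differences of 0.96 within replicates 1 and 2 and 0.11 within replicates 3 and 4, and lost its call without WT 2 or 3 or Supt7l KO 1 or 2 (0.0615 to 0.147) and with loess offsets (0.0652). Zic5 rose by 0.51 (adjusted p = 0.0123), lost without WT 2 or 3 or Supt7l KO 4 (0.0702 to 0.143) and with loess offsets (0.0584), and both lie in the distal block of chromosome 14. Pgk1, on chromosome X and a member of the glycolysis and reference gene lists, fell by 0.55 (adjusted p = 0.0434; DESeq2 0.290), but by 0.27 without WT 3, and lost its call without WT 2 or 3 or Supt7l KO 2, 3 or 4 (0.0796 to 0.562). The other 23 lists gave camera adjusted p-values of 0.144 to 0.836.

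Chromosome Y was the only chromosome called in a comparison. Its 7 peaks, at Uba1y, Eif2s3y, Uty and predicted genes, held 4 of 16195229 counts in Supt7l KO (2, 2, 0 and 0 per library) and 1146 of 19494317 in WT. That was 0.221 ± 0.256 CPM against 58.8 ± 4.80 in WT, 64.9 ± 23.4 in AID-Zzz3 and 66.3 ± 10.8 in AID-Yeats2 (SD, n = 4). The 1594 peaks of chromosome 14 from 60 Mb, a block chosen after its values were seen, had a median log2 value of 0.32 ± 0.046 in Supt7l KO, -0.18 ± 0.037 in AID-Zzz3 and -0.17 ± 0.026 in AID-Yeats2, and the WT libraries stood at 0.20, -0.25, -0.21 and 0.26. The 739 peaks of chromosome 17 from 70 Mb, chosen in the same way, stood at -0.51 ± 0.038, 0.30 ± 0.023 and 0.28 ± 0.0089, with WT at -0.28, 0.25, 0.30 and -0.26. All Supt7l KO libraries lay beyond all WT libraries in both blocks, and those of the ATAC lines lay within the range of WT on chromosome 14. The chromosome 14 block held 127 of the higher and 2 of the lower peaks of Supt7l KO, and 63 and 65 of the lower peaks of AID-Zzz3 and AID-Yeats2. The chromosome 17 block held 143 of the lower peaks of Supt7l KO.

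**Figure D3:**
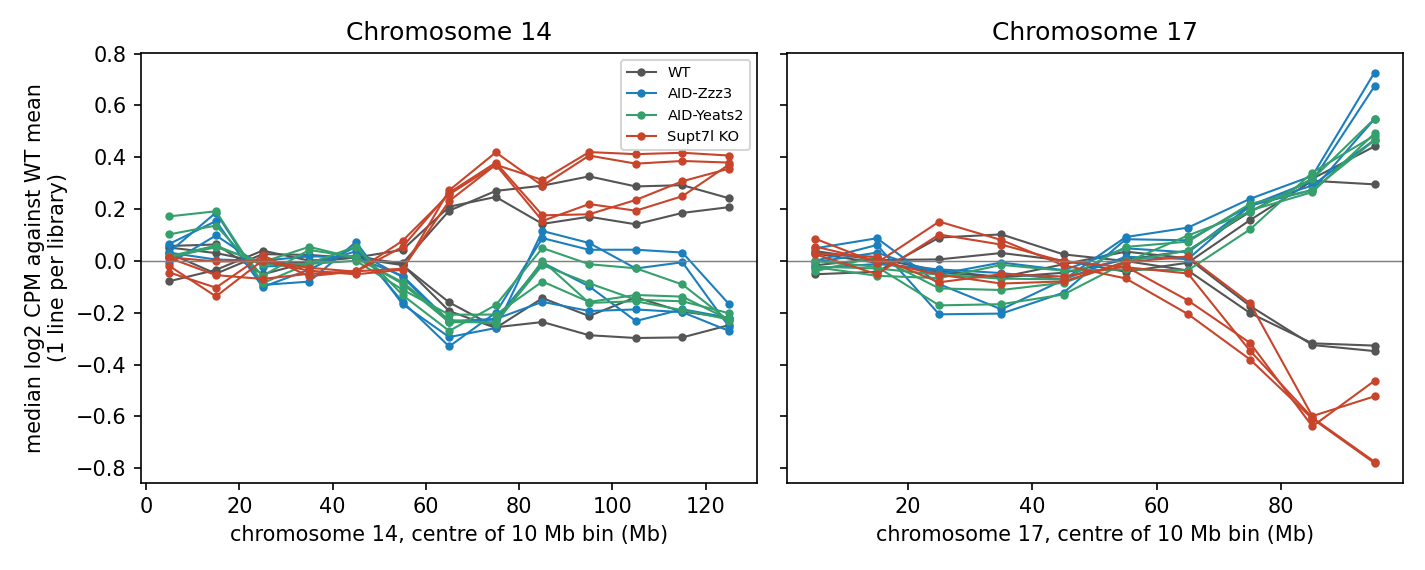
Median log2 CPM of peaks in bins of 10 Mb along chromosomes 14 and 17, against the WT mean, with 1 line per library coloured by genotype. The distal parts move as blocks, and the WT libraries part into a higher and a lower pair on both chromosomes.

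Without both blocks and chromosome Y, Supt7l KO had 69 higher and 214 lower peaks. The 1 peak at Supt7l, a promoter shared with Slc4a1ap, had a log2 change of 0.058 (adjusted p = 0.937). Within replicates 1 and 2 alone 32 peaks were higher and 84 lower, and within replicates 3 and 4 alone 129 and 218. Leaving out 1 library changed the count of higher peaks to 47 (WT 2), 29 (WT 3), 154 (Supt7l KO 2), 152 (Supt7l KO 3) or 101 (Supt7l KO 4), and that of lower peaks to 173 (WT 2), 136 (WT 3), 343 (Supt7l KO 1), 331 (Supt7l KO 2), 339 (Supt7l KO 3) or 283 (Supt7l KO 4). Higher peaks were 31.4% of the calls, and 20.7% with library totals alone.

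The ATAC lines were compared with Supt7l KO to ask whether these lines differ in the regions changed, a test of the difference itself. The contrast cannot tell the complex that was lost from the kind of loss or from the clone. The ATAC lines carried a degron triggered for 24 h. Supt7l KO was a knockout with nearly empty chromosome Y peaks and shifted blocks. The lines differed at 12235 peaks (edgeR), in a contrast of 8 libraries with 4. Promoters were lower in the ATAC lines and other sites higher. The imprinted genes Meg3 (2.55), Plagl1 (1.56), Nap1l5 (1.28) and Peg13 (1.76) were all higher in the ATAC lines on the log2 scale, while Klf5 (-1.05), Zic5 (-0.95) and Rpl10a (-0.99) were lower. Klf5 and Zic5 lie in the distal block of chromosome 14, which as a whole stood lower by 0.50 in AID-Zzz3 and 0.49 in AID-Yeats2 than in Supt7l KO. At Peg13, AID-Zzz3 2 (6.28 CPM) lay below all Supt7l KO libraries (6.58 to 11.26) and AID-Zzz3 4 just above them (12.5). The intron of Fam160a1 was higher by 1.65 (adjusted p = 6.56e-08) and that of Slc2a9 by 1.62, and the intron of Rb1 gave -0.37 (adjusted p = 0.165). Of the 5976 peaks higher in the ATAC lines, with a median log2 difference of 0.88, 10.8% lay at promoters (Fisher's exact test, p = 1.66e-224). Of the 6259 lower ones, with a median of -0.51, 64.1% did, against 27% of all tested peaks. With library totals alone 7379 peaks were higher and 4079 lower, and with loess offsets 4896 and 3619. The count was 4528 within replicates 1 and 2 and 5952 within replicates 3 and 4.

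Across peaks, fold changes of Supt7l KO correlated with those of AID-Zzz3 at r = 0.0991 and of AID-Yeats2 at r = 0.0746, below the means of 0.471 and 0.470 in simulations of unchanged groups that share WT. With separate WT libraries the values were -0.242 to 0.00566 and -0.263 to -0.0179. Called in opposite directions were 21 peaks of AID-Zzz3 and Supt7l KO and 29 of AID-Yeats2 and Supt7l KO, against 8 and 7 that were higher in both and 1 and 0 that were lower in both.

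The authors' own table, which is named for the day as a batch, called 666 higher and 330 lower peaks for AID-Zzz3, 589 and 311 for AID-Yeats2, 308 and 594 for Supt7l KO, and 0 between AID-Yeats2 and AID-Zzz3 (DESeq2, adjusted p under 0.05). Of the peaks called here, 596, 504 and 629 were also called there, and the log2 fold changes correlated across peaks with r = 0.999.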

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

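Tests chosen only after the result was seen were those of signal compression, CpG-rich sequence, copy number, the replicate sets, WT libraries taken from Supt7l KO cells and shared WT libraries, and the splits of each mutant against WT and of the gene lists.

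The ATAC lines and Supt7l KO moved apart at promoters. Promoter minus other peaks differed from Supt7l KO by -0.26 on the log2 scale in AID-Zzz3 and by -0.28 in AID-Yeats2 (exact permutation p = 0.0286 for each, the smallest possible), and 12235 peaks differed between these lines. Lower totals of counts in peaks in the mutant libraries are argued against as the cause. At least 96.8% of each line's difference from WT was left after all libraries were thinned to equal totals in peaks. Compression of strong against weak peaks is argued against as the whole cause, since at least 58.6% was left among peaks of like mean count. CpG-rich sequence, whatever its distance to a TSS, may account for the pattern, since the 340 CpG-annotated peaks over 3000 bp from a TSS showed at least 95.8% of the promoter value in each line. These peaks were not matched in mean count to the other distant peaks, and unannotated promoters among them were not set apart. A specific role of ATAC and SAGA at CpG-rich sequence stays open as the biological explanation and was not tested. Degron lines and a knockout also differ in the kind of loss, which the design cannot separate from the complex.

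Distal chromosomes 14 and 17 moved as blocks in Supt7l KO, and the WT libraries parted into pairs there. The pairs were not confined to the blocks. Promoter minus other peaks was 0.0053 and 0.034 in WT 1 and 4, on the side of Supt7l KO, and -0.024 and -0.036 in WT 2 and 3. Pgk1, on chromosome X, stood at 34.6, 56.9, 76.0 and 33.2 CPM in WT 1 to 4. Comparisons with WT carry this difference between WT libraries, whose cause was not tested. On chromosome 14 from 60 Mb the difference from Supt7l KO was -0.50 in AID-Zzz3 and -0.49 in AID-Yeats2, and on chromosome 17 from 70 Mb it was 0.82 and 0.79. No p is given, since the blocks were chosen from these values. The structure of replicates 1 and 2 against 3 and 4 is argued against, since WT libraries within such a set differed by at least 0.44, and WT 1 and 4 were not Supt7l KO cells, since each had at least 52.9 CPM on chromosome Y. A difference in copy number of these segments between the cultures is a candidate explanation, since promoter and other peaks of a block shifted alike in Supt7l KO, to within 4.48% of the larger shift. Whether it goes with the genotype or with the clone was not tested, because no label gives the clone of a library.

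The fold changes of AID-Zzz3 and AID-Yeats2 against WT were correlated. Shared WT libraries are argued against as the whole cause, since the covariance of edgeR fold changes was still at least 0.045 when each line had its own WT libraries. Computed from mean log2 values instead, it was at least 0.0388. Of this second value at least 95.7% was left without the peaks of chromosomes 14, 17 and Y named above, and among peaks over 1000 bp from a TSS at least 96.6%. Neither the blocks nor the difference between promoter and other peaks therefore accounts for most of it. A shift that follows CpG-rich sequence or mean count among the remaining peaks was not removed by this test. A shared effect of losing either ATAC subunit is consistent with these values, as a hypothesis, and a shared history of both AID lines, such as the degron and its parental cells, was not tested.

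Chance was tested with other splits of the same libraries into groups of 4. For AID-Zzz3 against WT 1 of 35 splits, the real one, called as many as 683 peaks, and the highest other split called 15. This is the smallest share that 35 splits allow. The other splits mix the genotypes and take no account of the replicate sets or of clones. Chance differences between clones are therefore not excluded. The same held for AID-Yeats2 (1 of 35; 573 against 9) and Supt7l KO (1 of 35; 757 against 55). For the ATAC lines against Supt7l KO 1 of 100 splits drawn from 495, the real one, reached 12235. The highest other, 4372, drew replicates 3 and 4 of both ATAC lines and left all Supt7l KO libraries together in the same group. It therefore kept part of the real difference and does not show an effect of the replicate sets alone. Within these sets 4528 and 5952 peaks were called. For the counts of gene lists chance is not excluded: 6 of 35 splits reached the 3 lists of AID-Zzz3 (highest other 5), 3 of 35 the 3 lists of AID-Yeats2 (4) and 2 of 35 the 5 lists of Supt7l KO (9).

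A single library lay far from the other 3 of its genotype in 7 of 182 groups examined, where 9.10 were expected, since chance alone sets apart about 1 in 20 groups. The value is the gap to the nearest library as a share of the whole range. It was 0.931 for chromosome Y in AID-Yeats2 (library 4), 0.920 for the AC130844.1 peak in WT (library 1), 0.869 for Tmem14a in AID-Zzz3 (library 3), 0.846 for a further peak in WT (library 4), 0.875 for Wipi2 in WT (library 2), 0.902 for Ttc7b in AID-Yeats2 (library 3) and 0.832 for Nf2 in WT (library 2).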

How the results depend on the processing

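Fits without chromosome Y and the distal blocks, within replicate sets and with loess offsets joined to a block, and the promoter shares with loess offsets and with a block, were chosen only after the data were seen. Of the values that answer a comparison, 162 recomputed ones were the same, 87 moved and 4 reversed. Of those for single peaks and lists, 960 kept their call, 197 lost it and none reversed. All 84 named peaks kept their sign in every fit run. Where no cause is given, the cause was not tested.

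The numbers of replicates gave little sign of pairing beyond the sets of replicates 1 and 2 and of 3 and 4. Between lines, deviations correlated at a mean of 0.0561 for the same number and 0.0542 for the other number of a set. Of 16 libraries, 9 correlated best with their own number. With a replicate block for each number, higher and lower peaks came to 754 and 503 (AID-Zzz3), 678 and 480 (AID-Yeats2) and 404 and 735 (Supt7l KO), of which the first 5 moved. With a block for replicates 1 and 2 against 3 and 4 they came to 781 and 508, 707 and 496, and 413 and 769, with all 683, 573 and 757 calls of the design without a block kept, and with loess offsets joined to this block higher peaks came to 801, 623 and 358. With replicates 1 and 2 only (fewer libraries) counts were 16 and 9, 11 and 11, and 32 and 84, and with replicates 3 and 4 only 222 higher in AID-Zzz3, 90 and 40 in AID-Yeats2, and 129 and 218 in Supt7l KO. For the ATAC lines against Supt7l KO these sets gave 4528 and 5952.

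With loess offsets lower peaks numbered 148 (AID-Zzz3) and 94 (AID-Yeats2). With a mean count of at least 50, which left 27078 peaks, they numbered 129 and 81, higher peaks 234 (AID-Yeats2) and 127 (Supt7l KO), and the ATAC lines and Supt7l KO differed at 5319. Stricter thresholds lower counts by construction. At an adjusted p under 0.01 counts were 88 and 45, 83 and 29, 56 and 153, and 5937 between the ATAC lines and Supt7l KO, and at a change of at least 1.5-fold 158 lower (AID-Zzz3), 128 lower (AID-Yeats2) and 7452. Without chromosome Y and the distal blocks Supt7l KO had 69 higher and 214 lower peaks, fewer than the calls outside those regions in the fit of all peaks.

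Leaving out each library gave 146 (without AID-Zzz3 3) to 573 (AID-Zzz3 2) higher and 70 (WT 4) to 363 (AID-Zzz3 2) lower peaks in AID-Zzz3. It gave 127 (WT 4) to 293 (WT 2) and 40 (WT 4) to 190 (WT 3) in AID-Yeats2, and 29 (WT 3) to 315 (WT 1) and 136 (WT 3) to 616 (WT 1) in Supt7l KO. It gave 0 to 1 (without AID-Zzz3 4) between AID-Yeats2 and AID-Zzz3, and 8417 (without Supt7l KO 2) to 12657 (without AID-Zzz3 2) between the ATAC lines and Supt7l KO.

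Reversed were the promoter share of higher peaks in Supt7l KO, 39.1% in the main design, 24.2% with loess offsets and 15.9% without chromosome Y and the blocks, and the correlations of Supt7l KO with AID-Zzz3 (-0.0114) and AID-Yeats2 (-0.0557) with a mean count of at least 50, where that of AID-Zzz3 with AID-Yeats2 rose to 0.727. Gene lists called were 3, 3 and 5 with camera, 0, 0 and 0 with an estimated correlation, 18, 17 and 15 with fry, and 1 (AID-Zzz3) and 3 (Supt7l KO) with loess offsets.

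Simulated 1.5-fold changes were found in at most 19.4% of peaks, so small changes would often be missed. Motif shares were not run.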

Other observations

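The comparison of repeat families was chosen only after the data were seen. Peaks over 1000 bp from a TSS on some repeat families were higher in the ATAC lines. The median of all peaks this far from a TSS was itself 0.033 to 0.081 in the AID-Zzz3 libraries, 0.060 to 0.069 in AID-Yeats2 and -0.031 to -0.019 in Supt7l KO, against -0.0012 to 0.024 in WT. LINE elements of the L1 family, a large class of retrotransposons (1842 peaks), were higher than in WT by 0.20 on the log2 scale in AID-Zzz3 and by 0.18 in AID-Yeats2, in 4 of 4 libraries each (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0476 over 15 tests). Endogenous retroviruses of the ERVK class (4724 peaks) were higher by 0.095 and 0.083 and those of the ERV1 class (697 peaks) by 0.0996 and 0.092 in AID-Zzz3 and AID-Yeats2, with the same p. In Supt7l KO the ERV1 peaks were lower by the same test, at -0.12, as were the ERVL-MaLR peaks (2685), at -0.074. The medians of L1 (-0.026, exact permutation p = 0.314) and ERVK (-0.044, 0.143) did not pass. ERVK peaks still made up 18.9% of the called lower peaks this far from a TSS in Supt7l KO (85 of 450). They were 8.97% of the higher ones (13 of 145) and 9.29% of all tested ones. In the ATAC lines ERVK peaks were also frequent, among the higher peaks this far from a TSS, at 15.9% in AID-Zzz3 (61 of 384) and 16.9% in AID-Yeats2 (55 of 326). L1 peaks made up 10.2% of such higher peaks in AID-Zzz3 and 5.21% in AID-Yeats2, against 3.62% of tested ones. The L1 share in AID-Yeats2 did not pass at an adjusted p under 0.05. ERVL-MaLR peaks were higher in AID-Yeats2 by 0.041 (adjusted p = 0.0476), with 0.016 in AID-Zzz3 (exact permutation p = 0.229), no more than the shift of all such peaks, and ERVL peaks (650) passed in no line (0.034, 0.032 and -0.015). These values share the scale of the promoter shift and were not separated from it.

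Lists that camera called in no comparison follow with the median log2 changes of their promoters in AID-Zzz3, AID-Yeats2 and Supt7l KO and the smallest adjusted p, against medians of all promoters of -0.11, -0.12 and 0.090. Naive pluripotency promoters (29 measured) stood at -0.13, -0.13 and 0.15 (0.281), and Pou5f1, Sox2 and Nanog, named after their values were seen, passed in no comparison. Formative and primed pluripotency promoters (11) stood at -0.20, -0.038 and -0.0023 (0.526), primitive endoderm (10) at -0.076, -0.099 and 0.089 (0.758) and trophoblast (12) at -0.12, -0.12 and 0.20 (0.281). Mesendoderm (11) stood at -0.038, -0.068 and 0.023 (0.705), neuroectoderm (14) at -0.17, -0.15 and -0.035 (0.144), fibroblast (12) at 0.12, 0.011 and 0.082 (0.144) and germ line (15) at 0.039, -0.037 and 0.14 (0.281). SAGA subunits (20) stood at -0.10, -0.11 and 0.17 (0.258), ATAC subunits (14) at -0.17, -0.13 and 0.19 (0.226) and general transcription factors (31) at -0.15, -0.20 and 0.11 (0.154). Aminoacyl-tRNA synthetases (17) stood at -0.17, -0.22 and 0.11 (0.0867), glycolysis (19) at -0.15, -0.17 and 0.085 (0.526) and cholesterol synthesis (18) at -0.18, -0.20 and 0.11 (0.160). WNT targets (14) stood at -0.20, -0.17 and -0.0017 (0.278), FGF and ERK targets (18) at -0.054, -0.10 and 0.13 (0.144), and TGF-beta, BMP and LIF targets (16) at -0.10, -0.14 and 0.17 (0.281). Hox genes (18) stood at -0.14, -0.10 and 0.20 (0.579), ubiquitous reference genes (13) at -0.17, -0.13 and 0.14 (0.414) and the mitochondrial ribosome (53) at -0.11, -0.13 and 0.13 (0.195). Camera weighs a list against all other promoters, so its direction and the sign of the median can differ.

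Outside the distal blocks, 2 bins of 10 Mb were called in AID-Yeats2. The bin from 40 Mb of chromosome 15 stood at 0.25 ± 0.021 (132 peaks) and that from 40 Mb of chromosome 5 at 0.24 ± 0.043 (141 peaks; SD, n = 4).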
